A study of Mus musculus with 32 samples.

How the data were processed

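RNA was measured in 32 libraries of mouse parathyroid gland cells, the endocrine cells that make parathyroid hormone. Each library was made from 10 to 20 cells picked by hand for red fluorescence from a tdTomato reporter placed in the Pth gene, and cDNA was made with a SMART-Seq full-length kit, per the labels' protocols. The libraries form 8 experiments of 4 biological replicates. Control cells came from adult mice on a C57BL/6 background in 2 experiments, 1 labelled male at 8 weeks and 1 labelled female at 11 weeks. Cells derived from mouse embryonic stem cells (ESC) that had complemented Gcm2-deficient mouse hosts made up 4 experiments at 9 weeks, experiments 1 to 3 labelled female and experiment 4 labelled male. There was 1 experiment with ESC-derived cells from a Gcm2-deficient Wistar rat host (neonate, sex unknown) and 1 with grafted ESC-derived cells (labelled male, 12 weeks). The labels do not say which animals the replicates of an experiment came from, or whether a sex label describes the host or the donor cells.

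The authors quantified transcripts with Salmon, and GRCm39 is the genome build named, per the submitters' processing notes. The Salmon version and the transcript annotation are not given in the sources used here. The deposited tables give, per transcript and library, the expected count of reads, the TPM (an abundance scaled for transcript length and library size) and the effective length. Expected counts were the basis of all main tests, and TPM and effective length served only for alternatives. The tables list 116747 transcripts, of which 115685 matched a gene by Ensembl transcript identifier in GENCODE release M21. That release describes GRCm38, so it supplied gene names and types only and no coordinates are given. The other 1062 transcripts held 0.49% of all reads and were left out of the gene tables. Expected counts were summed to 35458 genes and rounded to whole numbers per gene and library.

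Depth was 29471254 to 32264864 reads per library in control experiment 1 and 9470744 to 15098391 in the other 28 libraries. Between 11556 and 13429 genes had at least 1 read. No unique molecular identifiers were used, so counting intervals and floors cover counting error only. Duplicate deposits were checked by a chi-square statistic over genes for the 48 pairs of libraries within an experiment. The lowest ratio of chi-square to degrees of freedom was 42.3, so no pair agreed within sampling noise and every library was kept.

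Sex and age are constant within an experiment, so the experiment is the unit in which an arm repeats. Counts were summed per experiment and the 8 sums were fitted in 1 model with a coefficient per arm, using edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, default expression filter, Benjamini-Hochberg adjustment). The contrasts taken from it were mouse host against control, rat host against mouse host, and graft against mouse host. The rat host and the graft have 1 experiment each and are assumed to vary between experiments like the other arms. The fit has 4 residual degrees of freedom. Differences within an arm were tested on single libraries with the same tool, for 4 against 4 control libraries and as an F-test among the 4 mouse-host experiments. A gene was called at an adjusted p below 0.05. The p-values measure the spread between these samples, which may be partly technical.

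CPM values are read counts scaled to TMM-adjusted library sizes, averaged over the 4 libraries of an experiment and then over experiments. An SD is over experiments for the control and mouse-host arms and over 4 libraries for the rat host, the graft and single experiments. Where a gene had no read in an arm, the fold was taken against a floor of 3 reads over that arm. Where it had 1 to 3 reads, the ratio is given with an exact 95% counting interval.

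Before the data were examined, 23 gene lists and 16 lists of cell-type markers, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Adjustment was over 35 lists within a comparison. Of the listed symbols, 12 had no match, among them Xist, H19 and Meg3, which leaves the Y-linked genes as the only tested members of the sex-linked list. Bmal1, Atp5f1a, Atp5f1b and Atp5f1c had no match either. The circadian clock list was tested with 15 of 17 listed genes, and that of nuclear oxidative phosphorylation genes with 31 of 34. The rule named, for each arm comparison, up to 12 genes with the highest and 12 with the lowest log2 fold change among called genes. These had to average at least 8 CPM, carry a symbol not of the Gm or Rik kind, and have every experiment of 1 arm above every experiment of the other. It also named the 4 members with the smallest p of each called list, the 8 genes with the smallest p in the tests within an arm, and all parathyroid and sex-linked genes. Some genes are not reported here and were also left out of the search for libraries that stood apart. Other genes named were chosen after their values were seen, and the text says so.

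The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by 2-, 4- or 16-fold. For mouse host against control, 43.3% of the 4-fold and 60.6% of the 16-fold changes were called among 15698 genes. For rat host against mouse host these shares were 22.4% and 57.6%, and for graft against mouse host 20.9% and 51.5%. For the control experiments the shares were 46.3% and 71.2% among 11544 genes, and for the F-test 47.8% and 72.7% among 12195. No simulated change was called in the wrong direction. Unchanged genes made up 12 of 89 calls for mouse host against control and 6 of 60 for the rat host. For both, this share of false calls was above the level set by the adjusted p threshold. Unchanged genes made up 2 of 51 calls for the graft, 3 of 87 for the control experiments and 2 of 86 for the F-test.

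The alternatives were DESeq2 1.42.0, limma voom with experiment as a random effect, single libraries without and with a replicate block, median-ratio scaling, no expression filter, Pth left out, length-scaled counts and limma-trend on log2(TPM + 1). Further alternatives were host sex as a covariate in a fit without the rat host, the sexes apart on single libraries, and each library or experiment left out. Chosen after seeing the data were control experiment 1 thinned to about the mean depth of the other libraries, the F-test without each experiment, and the list tests without each experiment. Figures were drawn with matplotlib.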

Results

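Parathyroid cells derived from mouse ESC by blastocyst complementation, in which donor cells fill the place of an organ the host embryo cannot make, were compared with native parathyroid cells. The data are 32 bulk RNA-seq libraries of 10 to 20 picked cells each, with 4 libraries in each of 8 experiments. There were 8 control libraries from 2 experiments, 16 from ESC-derived cells in mouse hosts (4 experiments), 4 from ESC-derived cells in a rat host and 4 from grafted ESC-derived cells. The 4 libraries of control experiment 1 held 29471254 to 32264864 reads each, and the other 28 libraries 9470744 to 15098391 reads. Chga, which encodes the secretory granule protein chromogranin A, took 20.0% of reads on average over the 32 libraries, and Pth, which encodes parathyroid hormone, took 8.70%. Cells were picked on a reporter in the Pth gene, so the presence of Pth reads is a result of that choice.

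The hosts lacked Gcm2, the transcription factor gene needed to form the parathyroid gland, so Gcm2 is given in every sample first. Gcm2 was present in every one of the 32 libraries, between 490 CPM in a control library and 1475 CPM in a mouse-host library. The control experiments averaged 614 ± 91.9 and 703 CPM, and the mouse-host experiments 679 ± 121, 1007 ± 93.2, 1344 ± 143 and 828 ± 129 CPM in the order 1 to 4 (SD, n = 4 libraries each). The rat-host cells averaged 707 ± 69.9 CPM and the graft 556 ± 57.1 CPM (SD, n = 4).

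**Figure D1:**
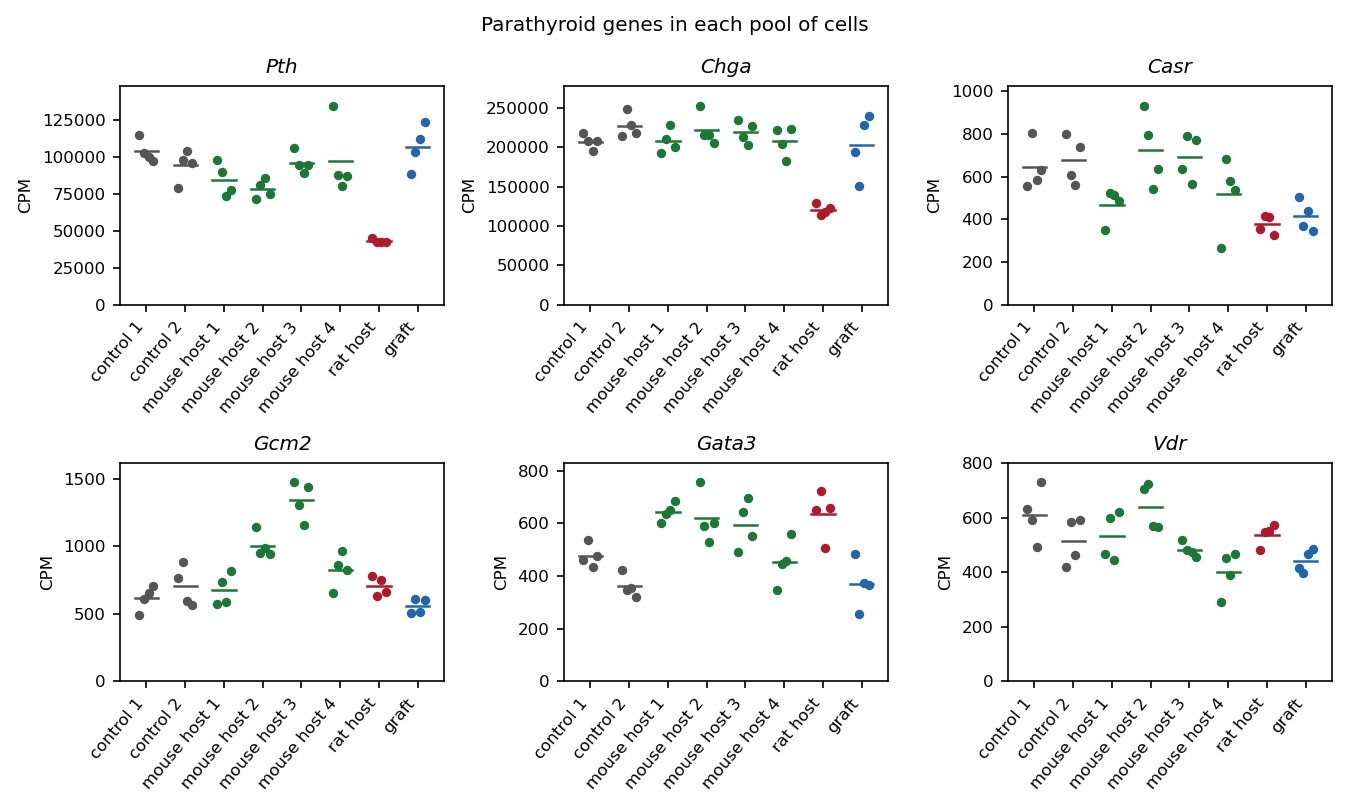
CPM of 6 parathyroid genes (vertical axes, linear from 0) in each library, by experiment (horizontal axes), with points for libraries and lines for means of 4. Pth and Chga in the 4 rat-host libraries lie below the mouse-host mean, at 43089 and 120910 CPM on average.

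Whether ESC-derived cells in a mouse host resemble native cells was tested with 4 experiments against 2. No parathyroid gene was called between the arms. Pth averaged 89186 ± 9212 CPM in mouse-host cells and 99163 ± 6692 CPM in control cells (SD over experiments), a log2 fold change of -0.16 (SE 0.10). The labels give 1 reporter allele of Pth in control cells and do not state the number in the donor ESC, so a difference in Pth alleles cannot be separated from this comparison. Casr, the calcium-sensing receptor that sets hormone release, had -0.12 (SE 0.19), Chga -0.02 (SE 0.07) and the vitamin D receptor gene Vdr -0.13 (SE 0.19). Kl, the co-receptor for FGF23, had -0.17 (SE 0.19), and the developmental regulators Eya1 and Tbx1 had 0.14 and 0.08. The largest differences among the 12 parathyroid genes were in Fgfr1 (28.4 against 15.8 CPM, log2 fold change 0.81, SE 0.24), Gcm2 (964 against 659 CPM, 0.56, SE 0.25) and Gata3 (578 against 419 CPM, 0.47, SE 0.19). None of these 12 passed the edgeR quasi-likelihood test, with Benjamini-Hochberg adjusted p of 0.892 or more, and none passed when adjusted over the list alone.

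Over all genes, edgeR called 0 of 15698 between mouse host and control, with 691 genes at an unadjusted p below 0.05, which is 4.40% of those tested. The smallest adjusted p was 0.892. Other tools called more, with 162 genes by DESeq2 (137 higher, 25 lower) and 42 by limma voom with experiment as a random effect (14 higher, 28 lower). Single libraries treated as independent gave 14 genes, and limma-trend on TPM gave 0. In simulated counts of this design 11.9% of 2-fold, 43.3% of 4-fold and 60.6% of 16-fold changes were called, so large differences could be missed as well as small ones. Of the 12 parathyroid genes, DESeq2 called Fgfr1 (adjusted p = 0.0168) and limma voom called Gcm2 (adjusted p = 0.0429). The edgeR test among females alone called Gata3 (adjusted p = 0.0236). Each was higher in mouse-host cells. The test among females treated libraries as independent and had control experiment 2 as its only control. Gata3 averaged 361 CPM there, against 477 CPM in control experiment 1.

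As groups, 4 of the 23 gene lists were lower in mouse-host cells than in control cells by camera with a preset correlation, and each call was lost when the correlation was estimated. All 13 mitochondrially encoded genes had negative log2 fold changes (median -0.55, camera adjusted p = 3.90e-05; adjusted p = 0.890 with an estimated correlation). Among them mt-Nd3 had -1.23 (SE 0.44), mt-Nd6 -0.95 (SE 0.34), mt-Atp8 -0.85 (SE 0.38) and mt-Atp6 -0.79 (SE 0.32). Of 34 cytosolic ribosomal protein genes 29 were negative, with a median of only -0.15 (camera adjusted p = 0.00290; adjusted p = 0.890 with an estimated correlation). Rpl27, Rpl37, Rplp2 and Rpl32 had -0.38, -0.43, -0.33 and -0.31. Of 16 genes for protein translocation into the endoplasmic reticulum 12 were negative (median -0.14, camera adjusted p = 0.0190; adjusted p = 0.890 with an estimated correlation), with Kdelr2 at -0.55, Sec61b at -0.38, Ssr3 at -0.43 and Spcs3 at -0.49. No member of these 3 lists was called by edgeR, over all genes or adjusted over the list alone. No marker list of another cell type was called, and the sums differed in direction. Of 8 fibroblast markers 8 were negative (547 against 883 CPM, camera adjusted p = 0.517). Both fibroblast means were raised by 1 library each, mouse-host experiment 2 replicate 4 at 2740 CPM and control experiment 2 replicate 3 at 3722 CPM. The other libraries of these arms held 128 to 615 CPM. Negative too were 6 of 7 MHC class II markers (83.6 against 206 CPM, camera adjusted p = 0.222) and 6 of 7 macrophage markers (1.89 against 11.4 CPM, adjusted p = 0.272). The share of reads on mitochondrial genes, a sign of cell and RNA state, was 2.87% and 2.83% in the control experiments and 1.69%, 2.11%, 2.31% and 3.11% in the mouse-host experiments 1 to 4. Without control experiment 1 the ribosomal list turned to the opposite direction (adjusted p = 0.660) and the translocation list was no longer called (adjusted p = 0.294). Without mouse-host experiment 2 the adjusted p of the ribosomal list was 0.123 and that of the translocation list 0.165, and without experiment 4 that of the translocation list was 0.0545.

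The sex-linked list, which held the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, was also lower (camera adjusted p = 0.0190; adjusted p = 0.890 with an estimated correlation). All 4 genes were lower when adjusted over the list alone and 0 over all genes. Ddx3y had 1 read over the 16 mouse-host libraries and 4613 reads over the control libraries, a ratio of 5106 (95% counting interval 916 to 201710). Eif2s3y had 3 against 4606 reads, a ratio of 1699 (581 to 8243). The log2 fold changes of Uty and Kdm5d were -6.37 and -2.31. Both are uncertain, since the female control experiment also held 55 Uty and 97 Kdm5d reads. Sharing of reads with X-linked copies may be the reason and was not tested. The fitted median of the list was -8.21, and -8.55 with Ddx3y and Eif2s3y at 3 reads. All Ddx3y and Eif2s3y reads in controls came from male control experiment 1, with 1891 to 2802 per library, and the female control libraries had 0. The libraries of mouse-host experiment 4 and of the graft, both labelled male, had at most 1 such read each. The list call was lost without mouse-host experiment 1 (adjusted p = 0.0760), experiment 2 (0.123) or experiment 4 (0.0578).

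**Figure D2:**
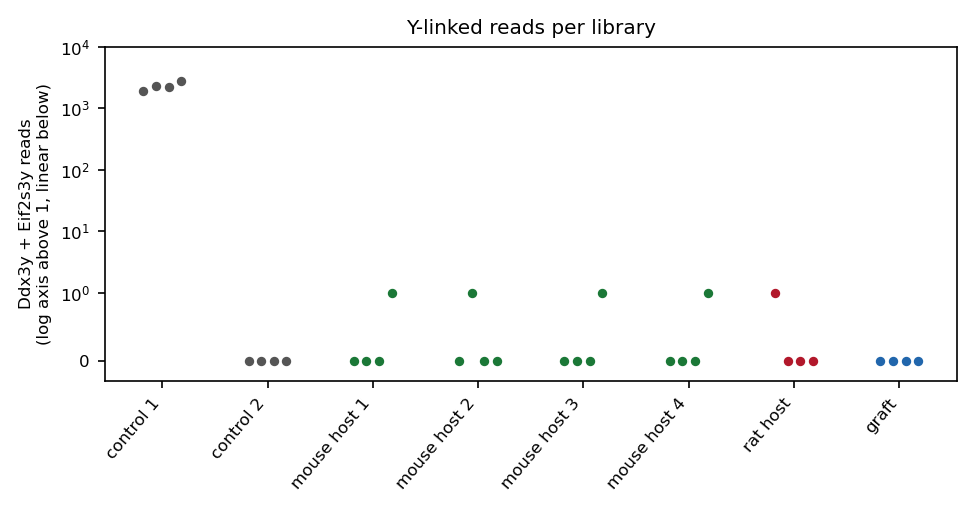
Summed reads of Ddx3y and Eif2s3y (vertical axis, logarithmic above 1 and linear below) in each library, by experiment (horizontal axis). The 4 libraries of control experiment 1 sit between 1891 and 2802 reads, and no ESC-derived library exceeds 1 read.

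Rat-host cells, picked from a neonate, were compared with adult mouse-host cells, so host species and age cannot be told apart. The rat-host cells had less of the hormone transcripts. Pth fell by 1.00 on the log2 scale (SE 0.14), to 43089 ± 1477 CPM (SD, n = 4 libraries) against 89186 ± 9212 CPM (SD, n = 4 experiments), with an edgeR adjusted p of 0.0354. Chga fell by 0.78 (SE 0.09, edgeR adjusted p = 0.0226), from 214460 to 120910 CPM. The other 10 parathyroid genes did not pass over all genes, with Kl at -0.85 (SE 0.26), Casr at -0.63 (SE 0.26) and Tbx1 at -1.33 (SE 0.89). The values of Gcm2 (-0.41), Eya1 (0.39), Gata3 (0.19), Vdr (0.11) and Fgfr1 (-0.04) were nearer 0. Adjusted over the list alone, 3 parathyroid genes were lower. Both hormone genes lost their call by limma-trend on TPM, where Pth had -0.64 and Chga -0.45. Without control experiment 1, control experiment 2, mouse-host experiment 3 or mouse-host experiment 4, the adjusted p of Pth was 0.0925, 0.0837, 0.0851 or 0.0683, and that of Chga 0.0853, 0.0670, 0.0724 or 0.0502.

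Among the named genes, the one that rose most in rat-host cells was Efemp1, which encodes the extracellular matrix protein fibulin-3, at 2032 ± 243 CPM against 126 ± 13.9 CPM (log2 fold change 4.08, SE 0.17, edgeR adjusted p = 0.000156). The tight junction gene Cldn4 rose by 3.58 (SE 0.55) and Nt5dc2 by 3.41 (SE 0.49). Next in order were the chromatin genes Hmgb2 at 2.82 (SE 0.44) and H2afx at 2.73 (SE 0.25), then Sh3bp5, the peptide hormone gene Edn3, the annexin partner gene S100a10, Nrep, Tspan14, Hmgn2 and the nuclear transport gene Rangap1, at 2.68 to 2.10. The adjusted p of these 11 genes after Efemp1 lay between 0.00833 and 0.0473.

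Genes that fell in rat-host cells included some that adult mouse-host pools expressed strongly. Tnmd, which encodes the membrane protein tenomodulin, dropped from 1826 ± 773 CPM to 14.6 ± 2.49 CPM (log2 fold change -6.90, SE 0.85, edgeR adjusted p = 0.0242). Gfra4, a receptor gene for the neurotrophic factor persephin, dropped from 282 to 3.36 CPM (-6.31, SE 0.55, adjusted p = 0.00833), and the immediate early gene Egr1 from 114 to 1.14 CPM (-6.51, SE 1.06, adjusted p = 0.0452). The glutamate transporter gene Slc1a1 had 4 reads over the rat-host libraries and 10850 over the mouse-host libraries (-9.59, SE 0.68, adjusted p = 0.00294). Adam33, Pacsin1, Klhl33, the integrin gene Itga7 and Rtn1 had 7 to 13 reads over the rat-host libraries and log2 fold changes of -8.44 (SE 1.34), -7.55 (SE 0.82), -7.52 (SE 0.47), -7.46 (SE 0.95) and -6.69 (SE 0.78). Lpo had 1 read in rat-host cells, a mouse-to-rat-host ratio of 606 (95% counting interval 109 to 23967), Tceal3 had 2 reads, a ratio of 467 (129 to 3862), and S1pr1 had 2 reads, a ratio of 376 (104 to 3104). Of 49 alternatives, the call was lost in 26 for Nrep, 17 for Rangap1, 15 for S1pr1, 14 for Egr1, 13 for Hmgb2, 11 each for Adam33 and Sh3bp5, 9 each for Cldn4 and S100a10, 8 each for Edn3 and Lpo, 7 for Tspan14, 5 each for Tnmd and Hmgn2, 4 each for Nt5dc2 and Itga7 and 3 each for Pacsin1 and Rtn1. It held in all 49 for Efemp1, H2afx, Slc1a1, Tceal3, Klhl33 and Gfra4. By limma voom the call was lost for Tnmd (adjusted p = 0.659), Egr1 (0.622) and S1pr1 (0.120). All 8 fibroblast markers were also negative, without a call as a list (median -7.47, camera adjusted p = 0.168), and 1 of them was called lower. The median was -6.92 with the 4 members that had at most 3 reads in an arm set at that floor. The markers summed to 71.5 CPM in rat-host and 547 CPM in mouse-host libraries, of which 1 reached 2740 CPM.

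**Figure D3:**
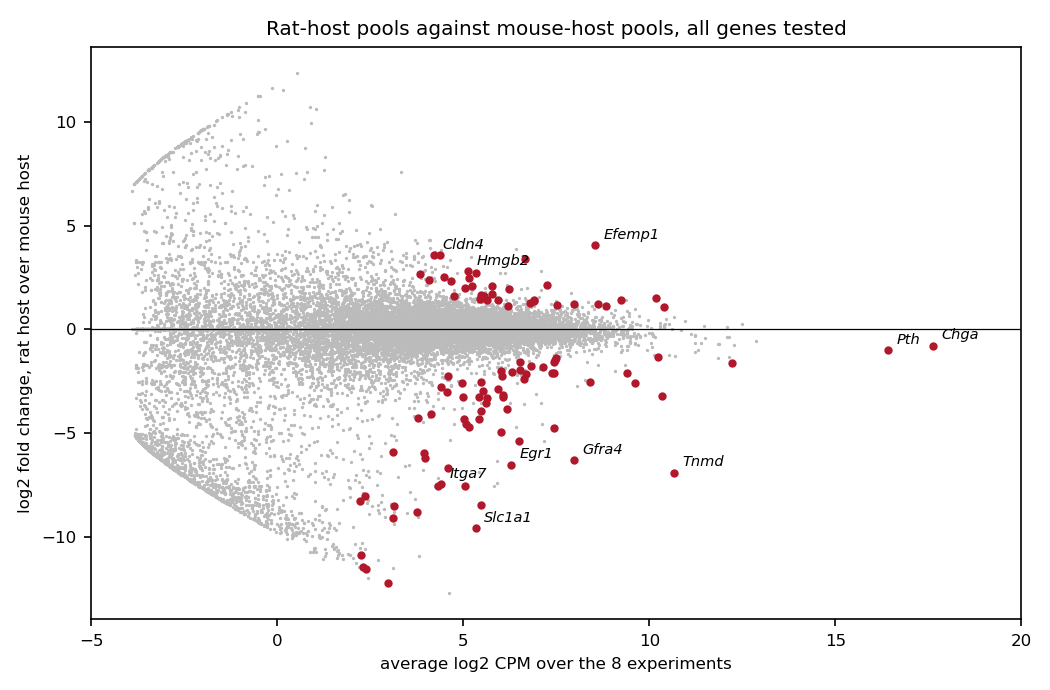
Log2 fold change of rat-host over mouse-host cells (vertical axis) against the average log2 CPM over 8 experiments (horizontal axis) for 15698 genes, with the 101 called genes in red. Efemp1 stands highest among the called genes with a symbol shown, at 4.08, and Slc1a1 lowest, at -9.59.

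In all, edgeR called 101 of 15698 genes between rat and mouse host, 34 higher and 67 lower, and 1816 genes had an unadjusted p below 0.05. The balance of directions depended on the method, with 782 higher and 261 lower by limma voom, 323 higher and 69 lower by limma-trend on TPM, 310 higher and 738 lower by DESeq2, and 326 higher and 450 lower in single libraries. The count was 12 without control experiment 1, 12 without control experiment 2, 15 without mouse-host experiment 4, 35 without experiment 3 and 52 without experiment 2.

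Among the gene lists, 4 were higher and 4 lower in rat-host cells with the preset correlation, and none with an estimated one. All 25 cell-cycle genes were positive, with a median of 3.27 (camera adjusted p = 2.49e-09; adjusted p = 0.606 with an estimated correlation). Ccna2, the cyclin A2 gene, was at 111 ± 81.4 against 8.74 ± 11.0 CPM, the mitotic kinase gene Aurka at 71.9 ± 79.4 against 6.32 ± 8.68 CPM, the replication gene Mcm4 at 72.4 ± 20.5 against 25.7 ± 9.60 CPM and Tyms at 69.2 ± 32.3 against 26.8 ± 12.4 CPM (SD, n = 4 libraries and n = 4 experiments). Single libraries overlapped, with Aurka at 0.0728 to 185 CPM in the rat host and 0 to 70.8 CPM in the mouse host, and Ccna2 at 5.68 to 199 and 0 to 82.4 CPM. No cell-cycle gene was called by edgeR, over all genes or adjusted over the list alone. Their summed level was 2133 ± 1341 CPM in the rat-host libraries (SD, n = 4), from 608 to 3797 CPM, and up to 1608 CPM in the 24 control and mouse-host libraries.

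Cholesterol synthesis genes were positive in 15 of 16 cases (median 1.04, camera adjusted p = 4.66e-05; adjusted p = 0.440 with an estimated correlation). Examples are Dhcr7 at 2.32 (SE 0.42), Insig1 at 2.50 (SE 0.72), Hmgcs1 at 1.45 (SE 0.26) and Mvd at 0.99 (SE 0.28), and 6 members were higher adjusted over the list alone, against 0 over all genes. Fetal and neonatal genes were positive in 8 of 12 cases (median 2.15, camera adjusted p = 0.00947; adjusted p = 0.440 with an estimated correlation), and 5 were higher adjusted over the list alone, against 0 over all genes. These included the fetal RNA-binding protein genes Igf2bp3 (26.7 against 1.59 CPM), Igf2bp2 (27.1 against 6.15 CPM) and Igf2bp1 (287 against 1 read, a ratio of 985 with a 95% counting interval of 175 to 39029), and Marcksl1 (175 against 90.9 CPM). The glycolysis list was also higher (median 0.47, camera adjusted p = 0.0303; adjusted p = 0.606 with an estimated correlation), although its mean was -0.24. Gapdh rose by 1.06 (SE 0.15) while the phosphofructokinase gene Pfkp fell by 2.96 (SE 0.35), and adjusted over the list alone 6 members were higher, Ldha (0.96) and Eno1 (0.89) among them, and 1 was lower. The glycolysis call was lost without control experiment 1 (adjusted p = 0.0551), control experiment 2 (0.0509) and mouse-host experiments 2 (0.0516), 3 (0.0523) and 4 (0.0587).

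**Figure D4:**
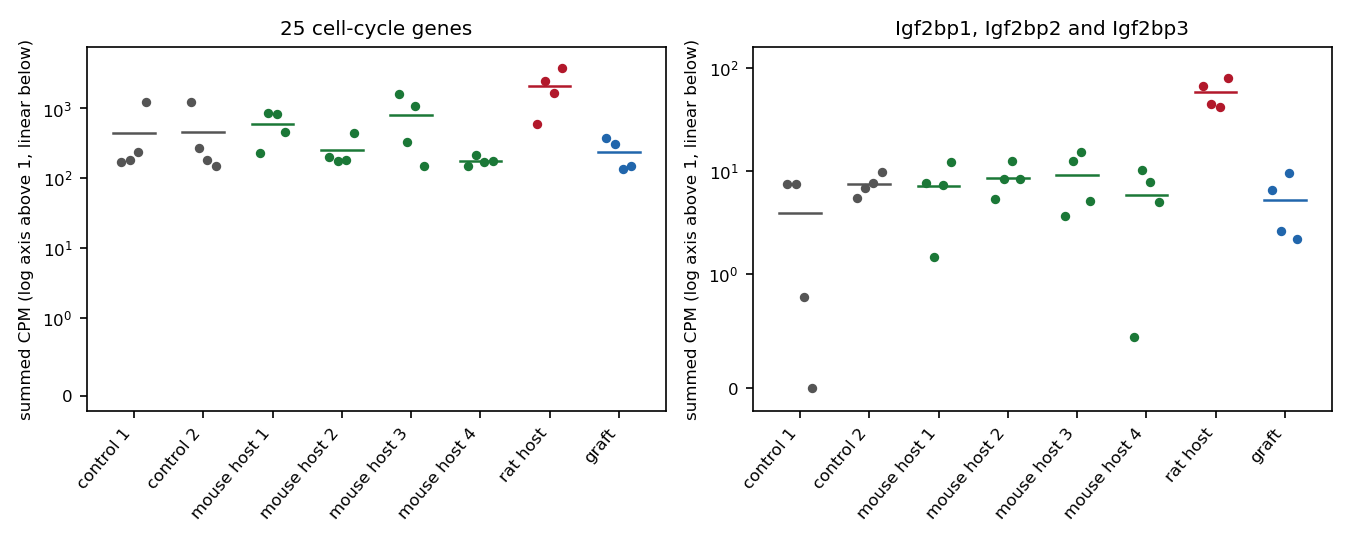
Summed CPM of 25 cell-cycle genes (left) and of Igf2bp1, Igf2bp2 and Igf2bp3 (right) in each library by experiment, on vertical axes logarithmic above 1 and linear below, with lines for means of 4 libraries. The rat-host libraries reach 608 to 3797 CPM on the left and 42.2 to 80.5 CPM on the right, where no control or mouse-host library exceeds 15.4 CPM.

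Lower in rat-host cells were the 13 mitochondrially encoded genes, all negative (median -1.02, camera adjusted p = 0.000338; adjusted p = 0.606 with an estimated correlation), with mt-Nd1 at -1.26, mt-Nd6 at -1.21, mt-Co1 at -0.77 and mt-Cytb at -0.72. The mitochondrial share of reads was 1.62 ± 0.097% in the rat-host libraries (SD, n = 4). Of the cytosolic ribosomal genes 31 of 34 were negative (median -0.27, camera adjusted p = 1.05e-05; adjusted p = 0.606 with an estimated correlation), with Rplp0 at -0.65, Rplp1 at -0.62, Rps6 at -0.49 and Rps9 at -0.47. Genes of MHC class I antigen presentation were negative in 11 of 14 cases (median -0.84, camera adjusted p = 0.00518; adjusted p = 0.440 with an estimated correlation). The peptide transporter gene Tap2 had -1.32 (SE 0.27), the immunoproteasome genes Psmb9 and Psmb8 had -3.40 (SE 0.74) and -3.45 (SE 0.91), and H2-D1, whose reads can be shared with related H2 genes, had -0.79 (SE 0.29). Adjusted over the list alone 3 of these were lower, against 0 over all genes. Immune cell marker lists were not called and differed in direction. MHC class II markers were negative in 6 of 7 cases (58.0 against 83.6 CPM). Macrophage markers summed to 0 against 1.89 CPM and T cell markers to 18.7 against 8.26 CPM. Circadian clock genes were negative in 10 of 15 cases (median -1.02, camera adjusted p = 0.0398; adjusted p = 0.606 with an estimated correlation). The clock repressor gene Nr1d1 fell by 2.24 (SE 0.35, edgeR adjusted p = 0.0412), and Nr1d2, Dbp and Tef had -1.12, -2.14 and -1.02; 2 members were lower adjusted over the list alone. The clock list was not called without control experiment 1 (adjusted p = 0.0551), control experiment 2 (0.0509) or mouse-host experiments 1 (0.0532) and 4 (0.116).

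Grafted cells were compared with mouse-host cells that had not been grafted, with age (12 against 9 weeks) part of the difference. Labelled sex was part of it too, since the graft and mouse-host experiment 4 were labelled male and mouse-host experiments 1 to 3 female. In the graft, 3 genes rose. Manf, an endoplasmic reticulum stress-induced secreted factor, reached 208 ± 6.67 CPM against 73.5 ± 5.16 CPM (log2 fold change 1.51, SE 0.18, edgeR adjusted p = 0.0434), Spink8, a protease inhibitor gene, 3735 ± 982 against 1044 ± 239 CPM (1.87, SE 0.23, adjusted p = 0.0453) and the kallikrein gene Klk1b3, one of a family of near-identical genes, 72.0 ± 13.8 against 5.80 ± 1.53 CPM (3.64, SE 0.43, adjusted p = 0.0434). No parathyroid gene was called, over all genes or adjusted over the list alone, and Pth had 0.27 (SE 0.13). Gcm2 had -0.78 (SE 0.34), Gata3 -0.64 (SE 0.25), Casr -0.53 (SE 0.26), Fgfr1 -0.49 (SE 0.31), Kl -0.29, Vdr -0.22, Tbx1 -0.13, Eya1 -0.12 and Chga -0.09.

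Of the 15 genes that fell, 13 met the criteria for naming, the 12 with the lowest log2 fold change are named here, and 7 of these had at most 3 reads over the 4 graft libraries. Fastkd5, which acts in mitochondrial RNA processing, and Uhrf1, which maintains DNA methylation, had 0 reads in the graft and 3544 and 2306 reads in mouse-host cells, at least 306-fold and at least 199-fold lower by a floor of 3 reads over the graft. Uhrf1 was also under 1 CPM in 6 of 16 mouse-host and 2 of 8 control libraries, Gpsm1 in 5 and 1, Cfap52 in 3 and 0 and Arsg in 2 and 0, while Fastkd5 was in none. Arsg, the replication origin gene Orc5 and Gpsm1 had 1 graft read each, with mouse-host-to-graft ratios of 953 (95% counting interval 171 to 37646), 723 (130 to 28575) and 392 (70.3 to 15494). Amph and Cfap52 had 3 reads each, with ratios of 263 (89.9 to 1276) and 241 (82.5 to 1171). Cmpk2, Fam185a, the endosomal tethering gene Vps8, the caspase gene Casp2 and Ppfibp2 had log2 fold changes of -6.58 (SE 0.84), -6.20 (SE 0.77), -5.86 (SE 0.54), -5.43 (SE 0.65) and -4.11 (SE 0.40), with edgeR adjusted p from 0.0195 to 0.0453. Of 50 alternatives, the call was lost in 16 for Manf, 19 for Klk1b3 and 20 for Spink8 among genes that rose. Among those that fell it was lost in 28 for Cmpk2, 27 for Gpsm1, 25 for Fam185a, 20 for Casp2, 17 for Cfap52, 15 for Arsg, 9 for Amph, 7 each for Uhrf1, Orc5 and Ppfibp2, 6 for Vps8 and 4 for Fastkd5. Correlation between libraries of the graft experiment was the lowest of the 8 experiments (mean r = 0.690 across genes, which are not independent replicates), and on average 3.69% of genes at 8 CPM or more elsewhere had 0 reads in a graft library, against 0.724 to 1.91% in the other experiments.

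In all, edgeR called 18 of 15698 genes between graft and mouse host, 3 higher and 15 lower, and 1940 genes had an unadjusted p below 0.05. The split was 180 higher and 1057 lower by DESeq2, 209 higher and 107 lower by limma voom, 101 higher and 33 lower by limma-trend on TPM and 208 higher and 269 lower in single libraries, and length-scaled counts gave 0 higher and 4 lower. The count fell to 2 without either control experiment, 6 without mouse-host experiment 1 and 0 without mouse-host experiment 2, 3 or 4. Without graft replicate 1, 2, 3 or 4 it was 53, 77, 67 or 64, and it was 5 to 10 without any one of 12 libraries: control experiment 1 replicate 1 (10), control experiment 2 replicate 4 (6), mouse-host experiment 1 replicates 1 (5), 2 (8) and 3 (9), experiment 2 replicates 1 (6), 2 (10), 3 (7) and 4 (10), experiment 3 replicate 3 (6), and experiment 4 replicates 1 (9) and 2 (7). With host sex as a covariate, in a fit without the rat host, it was 0.

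Of the gene lists, 4 were higher in the graft and none lower, and none of the 4 held with an estimated correlation. Endoplasmic reticulum translocation genes were positive in 15 of 16 cases (median 0.51, camera adjusted p = 2.28e-05; adjusted p = 0.682 with an estimated correlation), with Spcs1 at 0.83, Sec61b at 0.84, Ssr4 at 0.65 and Ssr3 at 0.78. Unfolded protein response genes were positive in 14 of 18 cases (median 0.60, camera adjusted p = 2.55e-05; adjusted p = 0.713 with an estimated correlation). Besides Manf, the chaperone gene Hspa5 had 0.82 (SE 0.13), Sdf2l1 0.99 (SE 0.19) and Dnajb9 1.39 (SE 0.32). Adjusted over the list alone, 6 translocation genes were higher, and 7 unfolded protein response genes were higher and 1 lower, against 0 and 1 over all genes. All 13 mitochondrially encoded genes were positive (median 1.04, camera adjusted p = 2.28e-05; adjusted p = 0.934 with an estimated correlation), with mt-Nd1 at 1.09, mt-Nd3 at 1.68, mt-Nd4 at 0.92 and mt-Cytb at 0.77, and 6 were higher adjusted over the list alone. The mitochondrial share of reads was 3.41 ± 0.521% in the graft (SD, n = 4). Nuclear genes of oxidative phosphorylation were positive in 23 of 31 cases (median 0.24, camera adjusted p = 0.000181; adjusted p = 0.934 with an estimated correlation), with Cox7c at 1.03, Cox7a2 at 0.61, Cox5a at 0.60 and Ndufa4 at 0.59 and none called in either way. The 2237 genes with the longest transcripts had a median log2 fold change of -0.05 in this comparison, and the 2237 with the shortest 0.09. Marker lists of other cell types were not called, and their sums differed in direction. Macrophage markers were at 8.94 against 1.89 CPM (5 of 7 positive, 5 with at most 3 reads in an arm, camera adjusted p = 0.221). Fibroblast markers were at 267 against 547 CPM and MHC class II markers at 48.0 against 83.6 CPM.

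The difference between the control experiments, where sex, age and experiment go together, gives a scale for differences within an arm. By edgeR on single libraries 2 of 11544 genes were called, both Y-linked and higher in the male experiment 1, and 622 had an unadjusted p below 0.05. Eif2s3y (37.6 ± 12.0 CPM) was at least 603-fold higher and Ddx3y (38.8 ± 20.9 CPM) at least 604-fold higher, against a floor of 3 reads over experiment 2, where both had 0 reads (edgeR adjusted p = 0.0141 and 0.0148). Next in order, and not called, were Pim3 (-1.28, SE 0.17, adjusted p = 0.0520), the clock output gene Dbp (1.15, SE 0.19, adjusted p = 0.110), Apba3 (1.38), Myo6 (-1.13), Phf3 (1.32) and Atp5g2 (0.70). None of the 12 parathyroid genes was called, with Gata3 at 0.39 (SE 0.12), Pth at 0.13, Chga at -0.14, Casr at -0.08 and Gcm2 at -0.20. The count was 168 by DESeq2, 0 with a replicate block, 0 without any one replicate of experiment 1, 1 without experiment 2 replicate 3 and 4 without experiment 2 replicate 4.

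Among the 4 mouse-host experiments, edgeR's F-test on single libraries called 165 of 12195 genes, with 1511 at an unadjusted p below 0.05. Gcm2 was among them (679, 1007, 1344 and 828 CPM, adjusted p = 0.00669), and no other parathyroid gene was. The uroplakin gene Upk3a stood at 1297 ± 760 CPM in experiment 1 and between 12.4 and 53.5 CPM in the others (adjusted p = 2.33e-05). The desmosomal cadherin gene Dsc1 was at 0.196 and 1.55 CPM in experiments 1 and 2 and at 90.1 and 230 CPM in experiments 3 and 4, and Spp1, the osteopontin gene, ran the other way, at 3020 and 2916 against 185 and 686 CPM. Anp32a, the kinetochore gene Spc24 and the phospholipid synthesis gene Pcyt1b were lowest in experiment 1 (44.0, 79.1 and 131 CPM), and the lysosomal protease gene Ctsz (1962 CPM) and Ptov1 (96.8 CPM) were highest there. The count was 794 by DESeq2, 19 among experiments 2 to 4, and 102 without experiment 4. Leaving out single libraries took it to 78 (experiment 1 replicate 2), 84 (experiment 1 replicate 4) or 105 (experiment 4 replicate 2).

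Experiment 1 of the mouse-host arm also stood apart in transcript length. Among 8950 genes, the 2237 with the longest transcripts (3805 nucleotides or more) lay lower than the 2237 with the shortest (up to 1748 nucleotides), by a difference of medians of -0.44 on the log2 scale relative to the other experiments. In mouse-host experiment 2 the difference was 0.33, and in the remaining 6 experiments it lay between -0.13 and 0.18.

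The remaining 23 lists tested were not called in any of the 3 arm comparisons, with camera adjusted p between 0.0939 and 0.980. These were the gene lists for parathyroid identity, pharyngeal pouch development, calcium sensing, the vitamin D and FGF23 axis, hormone secretion, hypoxia response, immediate early stress, p53 targets, interferon response, pluripotency and imprinting. The marker lists were thyroid follicular cell, erythroid cell, endothelial cell, fibroblast, pericyte or smooth muscle, macrophage, T cell, antigen-presenting cell, thymic epithelial cell, skeletal muscle, adipocyte and Schwann cell. Lists for thyroid C cell, B cell, kidney tubule and neutrophil had fewer than 3 tested members and were not tested. Median, mean and test differed in sign for several uncalled lists, such as interferon response in the rat host (median 1.22, mean -0.31) and unfolded protein response in mouse host against control (median -0.10, mean 0.75).

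Whole-profile similarity was computed as Pearson's r across 8950 genes on log2(CPM + 1) of experiments, where genes are not independent replicates. The control experiments correlated at 0.924, control with mouse-host experiments at a mean of 0.917 (0.891 to 0.935) and mouse-host experiments with each other at 0.908 (0.892 to 0.938). The graft correlated with mouse-host experiments at 0.873 on average and the rat-host cells at 0.848.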

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

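The tests of depth and sex labels for the Y-linked reads, the tests of cell types, single cycling cells and age for the cell-cycle genes, and the test of depth for the graft were chosen after those results were seen.

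Ddx3y and Eif2s3y reads were near absent from all 24 ESC-derived libraries, including 8 labelled male. Lower depth was excluded, since male control libraries thinned to the depth of the others held at least 720 reads of both genes together, against at most 1 in any ESC-derived library. The labels may describe the host and not the donor cells, or may be wrong for mouse-host experiment 4 and the graft, where the highest library had 1 read, and these readings cannot be told apart. Donor cells with 2 X chromosomes could not be tested, because the mean log2 CPM of 4 X-linked genes differed between the female and male control experiments by only 0.25 (SE 0.16). The mean was also uneven among ESC-derived experiments, at 3.98 in mouse-host experiment 1 and 4.86 to 5.11 in the others. Under either reading of the labels, the sequenced cells had almost none of these transcripts, with 5 reads over the 24 libraries. This argues against donor cells that express the 2 genes at the level of male control cells. Reads alone do not show whether the donor cells lack a Y chromosome, which was not tested.

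Cell-cycle genes were higher as a list in the rat-host libraries with a preset correlation between genes (camera adjusted p = 2.49e-09), but not with an estimated one (adjusted p = 0.606). Fibroblast markers were lower in the rat host (ratio of summed CPM to mouse host 0.131, highest library 143 against a mouse-host mean of 547 CPM). This sum does not follow fibroblasts alone. In control experiment 1 the libraries held 214 to 615 CPM of it and 0 CPM of 6 collagen and matrix genes. Those 6 genes, chosen after their values were seen, summed to at most 1.24 CPM in any rat-host library, which argues against fibroblasts in these pools. Markers were counted on mouse transcripts only, so cells of the rat host could be undercounted in these tests of cell types, which was not examined. The values argue against mouse endothelial cells and macrophages, since the 9 markers of each summed to at most 0.676 CPM in any rat-host library. They argue against T cells by 0 CPM of Cd3e, Cd3d and Cd3g in the rat-host libraries, although the list of T cell markers summed to 18.7 against 8.26 CPM in mouse-host cells (camera adjusted p = 0.569), of which Lck made up 18.4 and 7.78 CPM. A few cycling cells in some pools remain a candidate, but the test could not decide. The lowest rat-host library had 608 CPM of cell-cycle genes, below the highest control or mouse-host library (1608 CPM). A lowest library set against the highest of 24 can fall below it under other causes too. The other rat-host libraries held 1680, 2445 and 3797 CPM, and the median of the 24 control and mouse-host libraries was 221 CPM. Neonatal age is another candidate for the cell-cycle difference. Igf2bp1, Igf2bp2 and Igf2bp3 summed to at least 42.2 CPM in every rat-host library, against at most 15.4 CPM in the control and mouse-host libraries. Age and host species cannot be told apart here, as 1 experiment carries both.

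Genes with few or no reads in the graft may reflect chance loss of transcripts in pools of few cells. In the graft, 35 genes at 8 CPM or more elsewhere had at most 3 reads over the 4 libraries, and in the 7 other experiments the number ran from 2 to 32, with 32 in mouse-host experiment 4. The share of such genes with 0 reads in a library was 3.69% in the graft and 0.724 to 1.91% in the others. The number of lost genes cannot decide between chance and real loss, since other experiments, such as the rat host with 25, may hold real losses too. Fastkd5, Amph and Casp2 were under 1 CPM in all 4 graft libraries and in no control, mouse-host or rat-host library. Vps8 and Ppfibp2 were so in 3 and 2 graft libraries and in none of the others. The other named genes that fell were also under 1 CPM in some library outside the graft. Lower depth was excluded, since graft libraries held 1.07 times the mean reads of mouse-host libraries. The effect of grafting itself remains open as untested.

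Of 35 splits of the 8 control libraries, only the real one called 2 genes, and the highest other called 1. These counts are small, but both genes are Y-linked and had 0 reads in control experiment 2. Of 100 groupings of the 16 mouse-host libraries, the real one included, only the real one reached 165 genes, and the highest other called 29. This argues against a random grouping of libraries as the source of that total. It does not exclude chance for any single gene, and libraries of an experiment may share an animal, which the labels do not say.

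Single libraries stood apart from the 3 others of their experiment in 17 of 239 groups of 4, where chance gives about 1 in 20, or 12.0. In shares of reads, Chga was 23.5% in control experiment 2 replicate 2 (others 21.3 to 21.5%), Pth was 12.1% in mouse-host experiment 4 replicate 1 (8.60 to 8.90%), and mitochondrial genes were 2.65% in mouse-host experiment 1 replicate 1 (1.33 to 1.42%). Among parathyroid genes, Pth was 45300 CPM in rat-host replicate 1 (42190 to 42440) and 134700 CPM in mouse-host experiment 4 replicate 1 (80670 to 87530). Tbx1 was 23.3 CPM in mouse-host experiment 4 replicate 3 (8.54 to 9.92) and Fgfr1 24.4 CPM in control experiment 2 replicate 3 (13.0 to 14.3).

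Among genes lower in the rat host, Slc1a1 was 8.06 CPM in mouse-host experiment 2 replicate 4 (50.6 to 57.9), Lpo 0.082 CPM in experiment 1 replicate 4 (13.8 to 22.5) and Tceal3 13.6 CPM in experiment 4 replicate 4 (24.5 to 26.7). S1pr1 was 0 CPM in mouse-host experiment 1 replicate 1 (26.3 to 33.6) and 0 CPM in experiment 4 replicate 2 (7.67 to 10.6). Adam33 was 147 CPM in experiment 3 replicate 2 (74.0 to 79.5) and Itga7 15.3 CPM in experiment 3 replicate 4 (47.9 to 53.7). Orc5, lower in the graft, was 11.9 CPM in mouse-host experiment 3 replicate 3 (14.3 to 14.8). The summed CPM of cell-cycle genes was 1222 in control experiment 1 replicate 4 (170 to 235) and 450 in mouse-host experiment 2 replicate 4 (179 to 202).

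The difference between mouse host and control differed between male and female experiments for Dsc1, by 6.48 on the log2 scale (4.44 in males, -2.04 in females; edgeR interaction test, Benjamini-Hochberg adjusted p = 0.00625). Libraries were treated as independent, with 1 male experiment per arm and 1 female control experiment, so sex cannot be separated from experiment. Dsc1 also varied between the female mouse-host experiments, at 0.196, 1.55 and 90.1 CPM. Reads on transcripts without a matched gene, which no comparison used, made up 0.608% in the rat-host libraries (lowest library 0.591%) against 0.425 to 0.519% in control, 0.420 to 0.572% in mouse-host and 0.502 to 0.579% in graft libraries.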

How the results depend on the processing

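Thinning of control experiment 1, the F-test without each experiment and the list tests without each experiment were chosen after seeing the data. With single libraries as units, mouse host against control, rat against mouse host and graft against mouse host gave 14, 776 and 477 genes, limma voom 42, 1043 and 316, and DESeq2 162, 1048 and 1237; DESeq2 gave 168 between the control experiments and 794 among the mouse-host experiments. Without the expression filter the rat host gave 173 and the graft 53, limma-trend on TPM gave 392 and 134, and length-scaled counts gave 4 for the graft and 1 between controls. With host sex as a covariate, in a fit without the rat host, the graft gave 0. On single libraries, mouse host against control gave 7 among males and 2 among females. Without control experiment 1, control experiment 2 and mouse-host experiments 2, 3 and 4 the rat host gave 12, 12, 52, 35 and 15 genes, and the graft 2, 2, 0, 0 and 0, with 6 without mouse-host experiment 1. Among mouse-host experiments the count was 19 without experiment 1 and 102 without experiment 4. With an estimated correlation 0 lists were called. The cause was not tested, except that fewer samples entered where some were left out.

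With experiments or single libraries left out in turn, the counts ran from 0 to 0 for mouse host against control, 12 to 127 for the rat host, 0 to 77 for the graft and 0 to 4 between controls. Among mouse-host experiments they ran from 78 to 202 without single libraries and from 19 to 130 without an experiment. The ribosomal list in mouse host against control turned to the opposite direction without control experiment 1 (adjusted p = 0.660; 6.22e-10 to 0.660 over the experiments left out), and the cause was not tested. Thinning gave 0, 103 and 17 genes. All 101 rat-host genes were among the DESeq2 calls, and 82 were called by limma-trend on TPM. Of 1273 alternative values for 26 named rat-host genes, 182 lost the call and 0 reversed, and of 750 for 15 graft genes 227 lost it and 0 reversed.

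With a replicate block on single libraries the counts were 4, 820 and 420 for the arm comparisons, 0 between controls and 111 among mouse-host experiments. Libraries with the same number did not deviate together (mean correlation -0.00734, from -0.14 to 0.116, with 1 of 112 pairs over 0.1), and 2 of 32 libraries were closest to their own number.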

Other observations

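All genes and libraries in this part were chosen after their values were seen. Among genes called lower in rat-host cells, Postn, which encodes the matrix protein periostin, stood at 67.9 against 394 CPM (log2 fold change -2.51, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0190). Clu and the secretory granule gene Scg5 had -3.18 and -3.82. The called graft genes not named in the report were Slc19a1, Ccdc166 and Chst12.

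Collagen and matrix transcripts were concentrated in a few libraries. The summed CPM of 6 such genes was 3235 in control experiment 2 replicate 3 (Col3a1 716, Dcn 1256) and 2352 in mouse-host experiment 2 replicate 4 (Col3a1 1143, Dcn 550). It was 410 and 85.5 in graft replicates 1 and 4, 22.9 in graft replicate 3, 21.3 in control experiment 2 replicate 1, 10.3 in mouse-host experiment 2 replicate 1, and at most 8.26 in the other 25 libraries.

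In mouse-host experiment 1, Myh10 (266 CPM), Golgb1 (36.1 CPM) and Ranbp2 (15.1 CPM) were lower than in experiments 2 to 4, and the lysosomal genes Ctsb (1139 CPM) and Lgmn (932 CPM) were higher. That experiment also had lower values for genes with long transcripts (difference of medians -0.44), and these gene differences were not separated from that trend. Besides Dsc1, the test for a difference between male and female experiments called Ly6k and Nsdhl, and 3 of 12716 genes in all, with the same limit that sex cannot be separated from experiment.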
